A study of Mus musculus with 4 samples.

How the data were processed

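CUT&RUN libraries were made from gastrocnemius muscle of 4-week-old male mice, 1 each for floxed Phf2 without Cre (Ctrl) and with Acta1-Cre (KO), with a PHF2 antibody or IgG. Groups were taken from the sample titles. Per the submitters' processing notes, Bowtie2, MACS2 and the mm10 build were used; their versions and settings, the handling of duplicates and the control library used in calling are not given in the sources used here. Peak names carry a single library each, so peaks were called per library. Reads and signal tracks were not analysed here.

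Each deposited list has 10 columns in the narrowPeak layout. The authors' fold enrichment is a ratio at the summit over the caller's local background, and the authors' -log10 p and -log10 q refer to the same background. The deposited score is the integer part of 10 times the -log10 q in every row and was not used otherwise. These values are the authors' own and served to describe, rank and filter peaks within a list. The lowest -log10 q was 1.40 in Ctrl PHF2, 1.77 in KO PHF2, 1.89 in Ctrl IgG and 1.71 in KO IgG.

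MACS2 computes its fold as (pileup + 1) / (background + 1) and its p from a Poisson upper tail, so both unknowns can be solved for each peak. In the PHF2 lists the pileup was a whole number of tags, within 0.005, times a single factor for all 309 distinct pairs of values in Ctrl (factor 0.649) and all 84 in KO (0.609). The best other factors gave 27.5% and 35.7%. A factor below 1 and backgrounds that follow whole control tags are the form MACS2 gives when a deeper library is scaled down to a control. The factors, the genome-wide background (0.361 and 0.343) and the fragment length of 292 bp gave a ratio of KO to Ctrl PHF2 library size of 1.013 and of control size of 0.950. IgG lists gave whole tags with no scaling, for the 71 Ctrl and 143 KO pairs of values that could be tested. On simulated peaks the method recovered 100% of tags. Tag numbers are those at the summit, not sums over a peak, and PCR copies may be among them if duplicates were kept. Poisson intervals are exact and cover counting error only.

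Starts were written 1-based. Overlap meant at least 1 bp and was computed in Python and checked against a brute-force search, in place of bedtools, which the design had named. Genes came from a RefSeq table of GRCm38.p6, the assembly behind mm10, with 21887 protein-coding genes on the autosomes, X and Y. That table holds no strand, exons or sequence. Distance to a transcription start was therefore replaced by distance to either gene end, exons and introns were merged as inside a gene, the planned sequence composition of peaks was not analysed, and random lists were not matched on promoter CpG content. Random placements kept each peak's width and chromosome, between the ends of the outermost annotated genes, with 1000 draws or 200 for lists of over 500 peaks.

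Shares carry Wilson 95% intervals, and a share of 0 carries the limit given by 3 counts. For each of 30 gene lists, the number of members with a Ctrl-only peak within 1 kb of a gene end was ranked among 10000 random lists of the same size drawn from all protein-coding genes. In simulations 95.5% of lists of 40 genes planted with an excess (25% of members at a peak, against 6% of all genes) and 1% of random lists passed the upper limit. The comparisons, the gene lists, the rule for named genes and most of the alternatives were fixed before the data were examined. Named genes were Phf2, the 20 genes with the highest fold enrichment at Ctrl-only peaks, up to 4 per list by the same order, the 5 highest KO PHF2 peaks, up to 5 peaks found in all libraries (none existed) and the 5 highest KO-only peaks at gene ends. Some genes that this rule names are not reported here. Further members and shared peaks were named after their values were seen. Alternatives were a stricter q, merged peaks, other overlap rules, other windows, the summit alone, all genes, the stronger 50% of each list, a Ctrl list of the KO list's length, nuclear chromosomes only and the nearest gene within 50 kb. A common p threshold, random lists matched on gene length in 10 classes and the location of IgG peaks on nuclear chromosomes alone were added after seeing the data. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.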

Results

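The series profiled sites bound by PHF2, a chromatin protein with a PHD finger and a JmjC demethylase domain, in the gastrocnemius, a calf muscle, of 4-week-old male C57BL/6 mice. CUT&RUN was used, in which an antibody directs a nuclease to cut and release the DNA around its target. Muscle from mice with floxed Phf2 and no Cre (Ctrl) was set beside muscle from floxed mice carrying Acta1-Cre, which is active in muscle fibres (KO). Each genotype was assayed with a PHF2 antibody and with IgG, a non-specific antibody that gives the background, which made 4 groups of 1 library each. The authors' lists held 1621 peaks for Ctrl PHF2, 161 for KO PHF2, 77 for Ctrl IgG and 152 for KO IgG. With no replicate in any group, each comparison describes these libraries and not the genotypes, no test across samples was possible, and all intervals are 95% intervals for counting error only. Read totals are unknown. The whole number of tags at each PHF2 peak summit was recovered from the authors' fold enrichment and -log10 p, and had a median of 15 in both lists, with quartiles of 13 and 19 in Ctrl and 13 and 18 in KO.

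Phf2 itself (Gene ID 18676, chromosome 13, 48801750 to 48870885 in mm10) held no peak in the Ctrl PHF2, KO PHF2 or Ctrl IgG list, within the gene or 1 kb around it. The KO IgG list had 1 peak inside the gene, at 48822891 to 48824114, with a fold enrichment of 8.59. Peak lists do not measure deletion of the gene or the amount of the protein, so the genotype labels were not checked by these files.

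The first comparison asked where PHF2 was found in muscle that keeps the gene. Of 30 gene lists, those above random lists at Ctrl PHF2 peaks included immediate early genes, atrophy and FoxO genes, and insulin signalling. Glycolysis and glycogen, circadian clock, splicing, sarcomere and myogenic regulation lists did so too. These lists hold a small part of all genes with such a peak. The list of olfactory and vomeronasal receptors had no member at one. Of the 1621 peaks, 1151 (71.0%, Wilson interval 68.7 to 73.2) lay within 1 kb of either annotated end of a protein-coding gene, against a median of 4.07% and a maximum of 5.86% in 200 random placements of peaks of the same widths. A further 25.3% lay elsewhere inside a gene, and 3.70% were intergenic, against 57.4% of random placements. The gene table gives no strand or exons, so a gene end here is a start or an end of transcription, and exons and introns were not told apart.

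**Figure D1:**
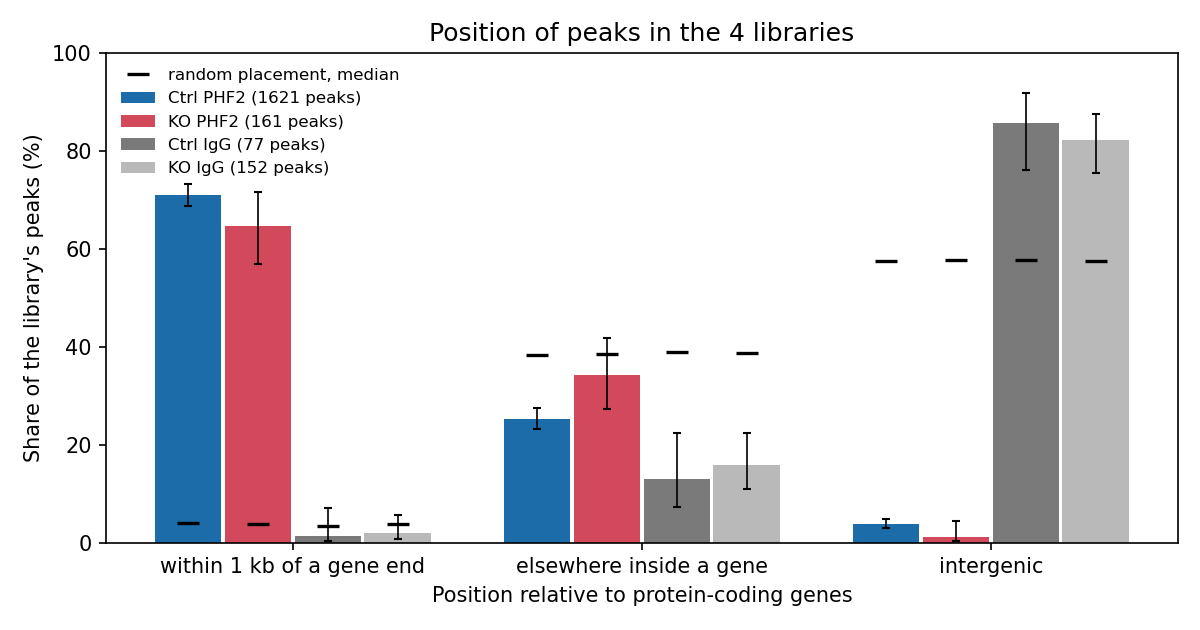
Share of each library's peaks (percent, y axis) within 1 kb of an end of a protein-coding gene, elsewhere inside such a gene, or intergenic (x axis). Bars are the 4 libraries with Wilson 95% intervals and black dashes are medians of random placements; both PHF2 libraries sit at 71.0% and 64.6% at gene ends, while the IgG libraries sit at 1.30% and 1.97%.

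No Ctrl PHF2 peak overlapped an IgG peak, and 1507 of them also overlapped no KO PHF2 peak. These are called Ctrl-only peaks, which means only that no KO peak was called there. KO tags at these sites were not measured. Ctrl-only summits had a median of 15 tags, and the lowest KO PHF2 peak had 10. The Ctrl-only peak with the highest fold enrichment at a gene end was at Jun (Gene ID 16476), an AP-1 transcription factor, on chromosome 4 from 95049856 to 95052321. Its fold enrichment was 16.1, with 37 tags at the summit (exact Poisson interval 26.1 to 51.0). It covered most of the gene, which runs from 95049036 to 95052222. Next came Ldlrad4, an inhibitor of TGF-beta signalling, at a fold enrichment of 14.6 with 29 tags (19.4 to 41.6), and the transcription factor gene Myc at 13.9 with 31 tags (21.1 to 44.0). The Ctrl-only peak at Myc (chromosome 15, 61985358 to 61988148) starts just beyond a KO PHF2 peak that ends at 61985356, so its place among the Ctrl-only peaks rests on the overlap rule. A peak at chromosome 19, 21272062 to 21273614, lay at Zfand5, a zinc finger gene of the ubiquitin system, and at the overlapping model LOC115489044, with a fold enrichment of 13.8. Ppm1l, which encodes a protein phosphatase, and Cpeb4, which encodes an mRNA-binding protein, both had 13.6. Arid1b, a subunit gene of the SWI/SNF chromatin remodeller, had 13.5 with 40 tags (28.6 to 54.5) in a peak of 3331 bp. Plpp1, a lipid phosphate phosphatase gene, had 13.1, and the transcription factor genes Irf2 and Vezf1 both had 12.5. Ppp2r5a, a regulatory subunit gene of protein phosphatase PP2A, had 12.2, as did a single peak inside the stress-activated kinase gene Mapk14, at an end that also lies within 1 kb of an end of its neighbour Slc26a8. The remaining genes of the leading 20 were Rnf150, the mineralocorticoid receptor gene Nr3c2, Rbm24, which encodes a muscle splicing regulator, Daam1, the kinase gene Jak1 and Zfp592, from 12.0 down to 11.6.

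In all, 1144 of 21887 protein-coding genes (5.23%) had a Ctrl-only peak within 1 kb of an end. Of 30 gene lists, 11 stood above the central 95% of 10000 random lists of the same size by percentile. For 1 of these 11 the count equalled the upper limit, and 2 lists stood below. Random lists were drawn from all protein-coding genes and were not matched on expression. A high count was therefore not told apart from activity of the genes in muscle. Immediate early genes, which respond within minutes to stimulation, had 9 of 22 members at such peaks, against a random upper limit of 3. Beside Jun and Myc they included Fosl2 (fold enrichment 11.3) and Jund (9.27), with Fos, Btg2, Ier2, Klf4 and Klf6. The list of atrophy, ubiquitin ligase and FoxO genes had 10 of 28, against a limit of 4. It held the muscle ubiquitin ligase genes Trim63 (7.41), Fbxo32 (6.31) and Fbxo30 (8.84), with Gadd45a (8.83), Foxo3, Nedd4, Cul3 and the conjugating enzyme genes Ube2d1, Ube2d2a and Ube2d3. Foxo3 and Klf6 count here through a small second peak, while their main peak was shared with the KO library. Insulin, IGF and mTOR signalling had 9 of 34, against a limit of 5, among them the receptor substrate gene Irs2 (9.07), Gsk3b (8.94) and Pik3ca (8.37).

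Metabolic lists were represented to differing degrees. Glycolysis and glycogen had 8 of 32 members, against a limit of 4, among them the muscle phosphoglycerate mutase gene Pgam2 (fold enrichment 10.02), Pkm (8.37), Ugp2 (7.32) and the glycogen synthase gene Gys1 (7.20). Fatty acid and mitochondrial regulators also had 8 of 32, led by the coactivator gene Ppargc1b (10.2) and followed by Ppard (6.19), Lpl (5.96) and Nrf1 (5.70). This excess was lost among the stronger 50% of peaks, where the list stood at percentile 58.7. The circadian clock list had 5 of 19, against a limit of 3: Rora (10.6), Bhlhe41 (8.83), Nr1d1 (6.34), Bhlhe40 (6.30) and Dbp. Oxidative phosphorylation had 7 of 89 members, within its random range of 1 to 9, with Ndufb1 (9.20) and Uqcrc1 (7.89) the strongest.

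Muscle structure and identity were also represented. Sarcomere genes had 8 of 42 members at Ctrl-only peaks, against a limit of 5: Des (9.98), Myot (8.37), Myom1 (7.61), Tmod1 (5.70), Cfl2, Flnc, Mybpc2 and Tpm2. Among the other 34, chosen for mention after the values were seen, were Acta1, Ttn and the myosin heavy chain genes Myh1, Myh2 and Myh4, which had no Ctrl PHF2 peak at a gene end. Myogenic regulators had 7 of 30, against a limit of 4, among them Tead1 (8.29), Mef2d (8.15), Myf6 (7.89) and Myod1. Excitation-contraction coupling had 4 of 25, at the limit of 4 and percentile 97.6: Trdn (7.41), Casq1 (6.26), Jph2 (5.96) and Jph1 (4.01). Among the stronger 50% of peaks sarcomere genes fell to percentile 92.9 and excitation-contraction coupling to 66.7. The latter list also left the upper range with all Ctrl PHF2 peaks (percentile 97.0), with peaks at or above the -log10 p of the weakest KO PHF2 peak (92.7) and against lists matched on gene length (96.6). The dystrophin complex list had 2 of 22, within its random range.

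Splicing and RNA processing had 20 of 117 members at Ctrl-only peaks, against a limit of 11, with Hnrnpa2b1 (9.78), Ddx39a (9.24), Ddx3x (8.37) and Sf3b1 (7.79). The single peak at Hnrnpa2b1 also counts for its neighbour Cbx3 among histone demethylases, methyltransferases and their readers. That list had 6 of 38, against a limit of 5, with Kmt2c (11.2), Setd1b (8.83) and Kdm3a (8.65). It fell from percentile 99.15 to 95.6, inside the central range, when random lists were matched on gene length. Histone genes had 10 of 101, at percentile 97.3, where neighbouring genes share peaks, as H2ac18 and H3c14 do. Their strongest peak was at H3f3a (11.5).

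Most of the other lists gave counts inside their random ranges. Ribosomal proteins had 3 of 82 members (Rpl36al, Rpl7 and Rpl21), mitochondrial ribosomal proteins 4 of 78 (Mrpl18, Mrpl1, Mrps18b and Mrpl48) and the proteasome 2 of 48 (Psmd11 and Psmd12). Translation factors and tRNA synthetases had 3 of 106 (Eif1ad, Eef2k and Eif3j1), and zinc finger genes 21 of 389, with Zfp568 (11.2), Zfp521 (9.01) and Zfp462 (8.37) after Zfp592. Autophagy and lysosome genes had 2 of 36 (Gabarap and Wipi1), stress response genes 2 of 28 (Nfe2l1 and Nfe2l2) and cell cycle genes 4 of 38 (Rb1, Trp53, Ccnd1 and Cdkn2c). Among markers of cells other than fibres, endothelial cells had 2 of 15 (Flt1 and Cdh5) and satellite cells, the muscle stem cells, 2 of 14 (Hes1 and Cxcr4). Over all Ctrl PHF2 peaks, shared ones included, the satellite cell list had 4 members and stood at percentile 99.6. Fibro-adipogenic and tenocyte markers (16 genes), immune markers (16 genes), pericyte, smooth muscle and Schwann markers (11 genes) and DNA repair genes (26 genes) had 0, which random lists of those sizes also gave. Olfactory and vomeronasal receptors had 0 of 1463, where random lists held 61 to 93, and keratins had 0 of 105, where random lists held 1 to 10. The keratin list stood at percentile 4.31 against lists matched on gene length, inside the central range.

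**Figure D2:**
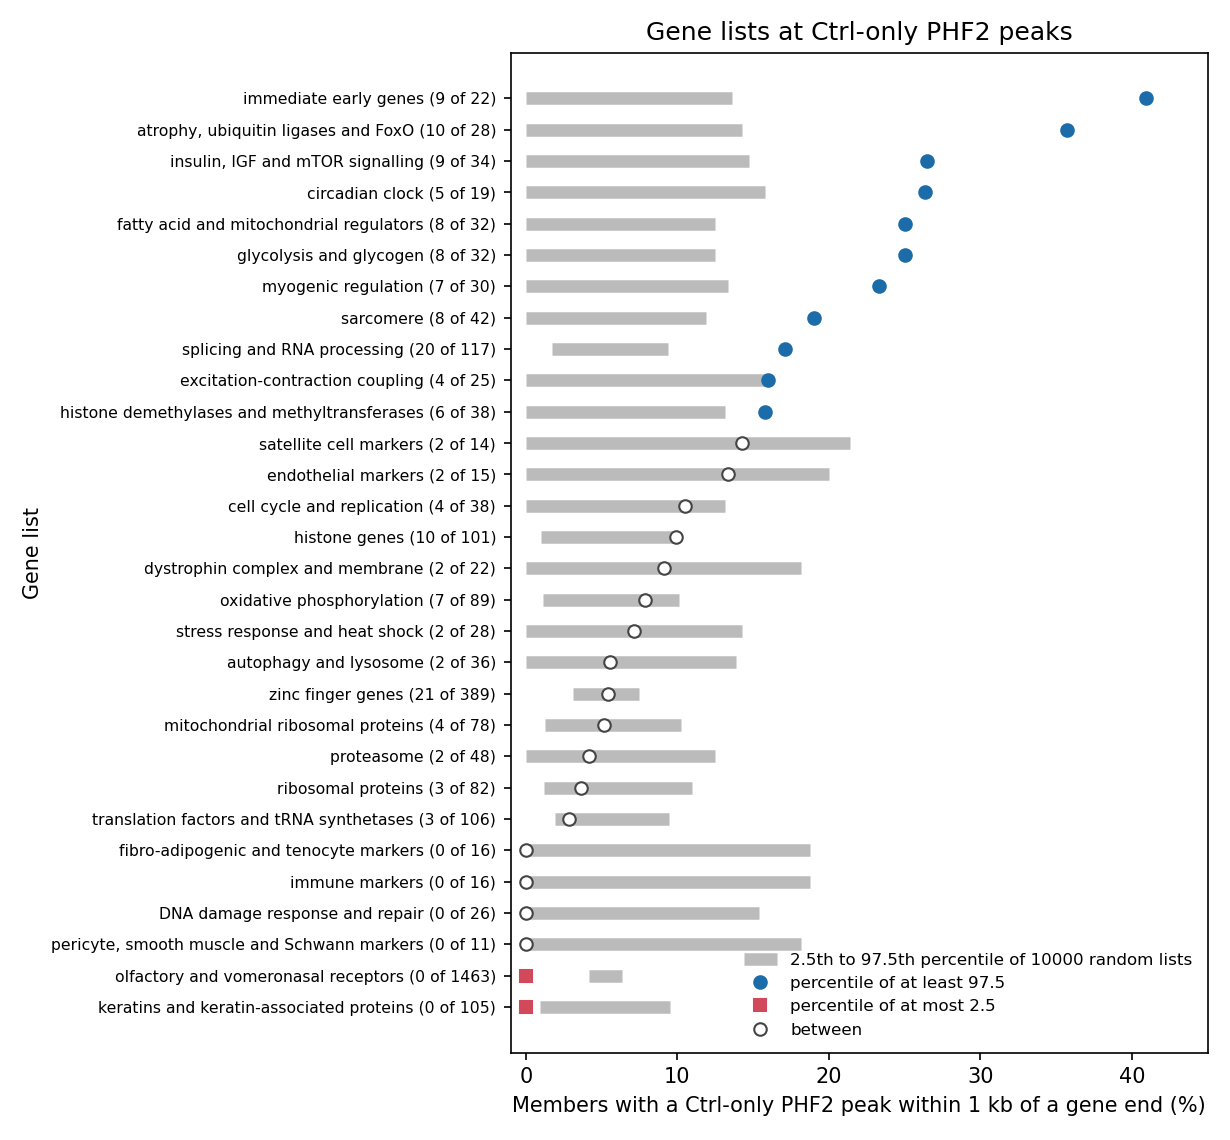
Percent of each gene list's members with a Ctrl-only PHF2 peak within 1 kb of a gene end (x axis) for the 30 lists (y axis, with counts). Points are the lists and grey bars the central 95% of 10000 random lists of the same size; immediate early genes (9 of 22) lie furthest to the right and olfactory and vomeronasal receptors (0 of 1463) lie left of their grey bar.

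Over the chromosomes, Ctrl PHF2 peaks were densest on chromosomes 11 (1.11 per Mb, exact Poisson interval 0.928 to 1.31) and 19 (1.06, 0.816 to 1.36), against 0.600 per Mb over all nuclear chromosomes. Per 100 protein-coding genes these chromosomes had 8.39 (7.03 to 9.93) and 8.79 (6.74 to 11.3) peaks, against 7.41 over all, which lies within both intervals. On that scale chromosomes 1 (10.05, 8.34 to 12.0), 10 (9.19, 7.409 to 11.3), 12 (10.6, 8.30 to 13.4) and 18 (10.96, 8.28 to 14.2) lay above 7.406, the overall value, and chromosome 7 (4.33, 3.48 to 5.34) below it. The X chromosome, present once in these male mice, held 23 peaks, or 0.135 per Mb (0.0854 to 0.202). By the same count of genes that was 2.38 peaks (1.51 to 3.57). The Y chromosome held 0. The intervals treat peaks as independent, though merging peaks within 1 kb left 1415 Ctrl PHF2 peaks. No allowance was made for comparing many chromosomes, and chromosome 10 cleared the overall value only narrowly.

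The second comparison asked which peaks the PHF2 antibody gave in muscle from mice with Acta1-Cre. The KO PHF2 list held 161 peaks, and 122 of them (75.8%, Wilson interval 68.6 to 81.7) overlapped a Ctrl PHF2 peak. They lay at genes such as Foxo1 and Foxo3, FoxO transcription factors that act downstream of insulin signalling, and Dusp1, Klf6 and Myc among the immediate early genes. Conversely, 114 of the 1621 Ctrl peaks (7.03%, 5.89 to 8.38) overlapped a KO PHF2 peak by at least 1 bp. The median of 1000 random placements of the KO peaks was 0 Ctrl peaks and the highest was 2. By gene, 84 of the 106 genes with a KO PHF2 peak at an end also had a Ctrl PHF2 peak there. Independent lists would share 5.93. Random placements did not keep peaks at gene ends, and neither figure shows that the KO peaks mark bound PHF2.

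The numbers still differed at a common threshold. The weakest KO PHF2 peak had a -log10 p of 6.19, and 1464 Ctrl PHF2 peaks reached that value. A reciprocal overlap of at least 50% left 1.85% of Ctrl peaks shared. Limiting the Ctrl list to its 161 peaks of highest fold enrichment, the length of the KO list, gave 33 shared peaks, or 20.5%. Ctrl peaks with a KO counterpart were wider than Ctrl-only peaks, with median widths of 1112 and 491 bp. Their median fold enrichments were 7.57 and 6.34 and their median summit tags 21 and 15. The share with a KO peak was 1.54% (0.659 to 3.55) in the fifth of Ctrl peaks with the fewest tags and 20.7% (16.6 to 25.4) in the fifth with the most.

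**Figure D3:**
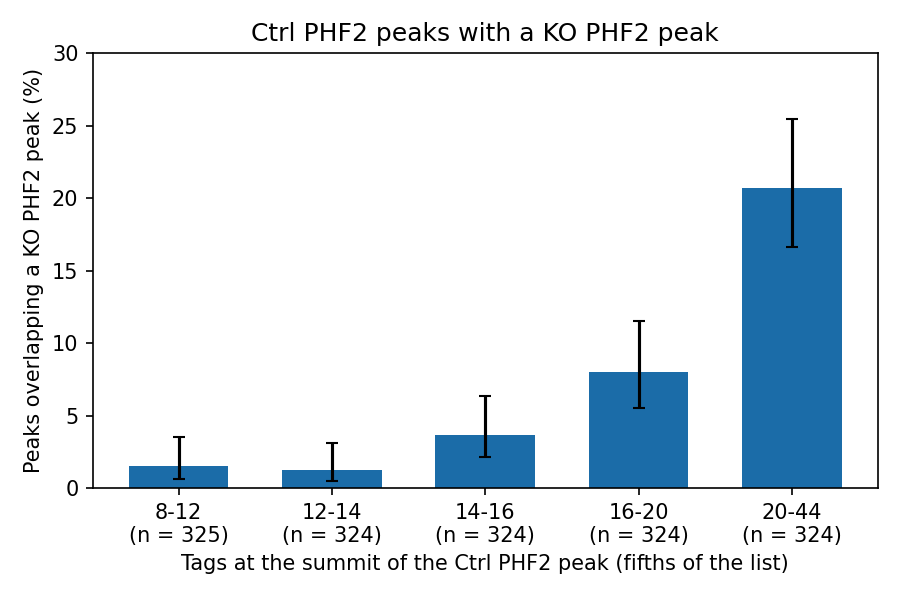
Percent of Ctrl PHF2 peaks that overlap a KO PHF2 peak (y axis) in 5 groups of peaks ordered by tags at the summit (x axis, with the range of tags and the number of peaks). Bars carry Wilson 95% intervals; the share is 1.54% in the group with the fewest tags and 20.7% in the group with the most.

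The KO PHF2 peak of highest fold enrichment was at Plpp3, a lipid phosphate phosphatase gene, on chromosome 4 from 105157395 to 105159683, with a fold enrichment of 12.5 and 26 tags (exact Poisson interval 17.0 to 38.1). It overlapped the highest of the Ctrl peaks, with 44 tags (32.0 to 59.1). The next were peaks at the adhesion receptor gene Adgrl2 (11.6), the homeobox gene Meox2 (11.6) and Foxo1 (11.3), then a second peak at Adgrl2 (10.7). At Foxo1 (Gene ID 56458) the KO peak ran from 52269259 to 52270196 on chromosome 3, within the Ctrl peak at 52267579 to 52270444, at the lower end of the gene. The KO summit had 24 tags (15.4 to 35.7) and the Ctrl summit 31 (21.1 to 44.0), a difference within the counting error. Over the 114 shared Ctrl peaks, the KO summit had fewer tags in 94, the same number in 5 and more in 15, with a median ratio of 0.725 (quartiles 0.590 and 0.907).

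**Figure D4:**
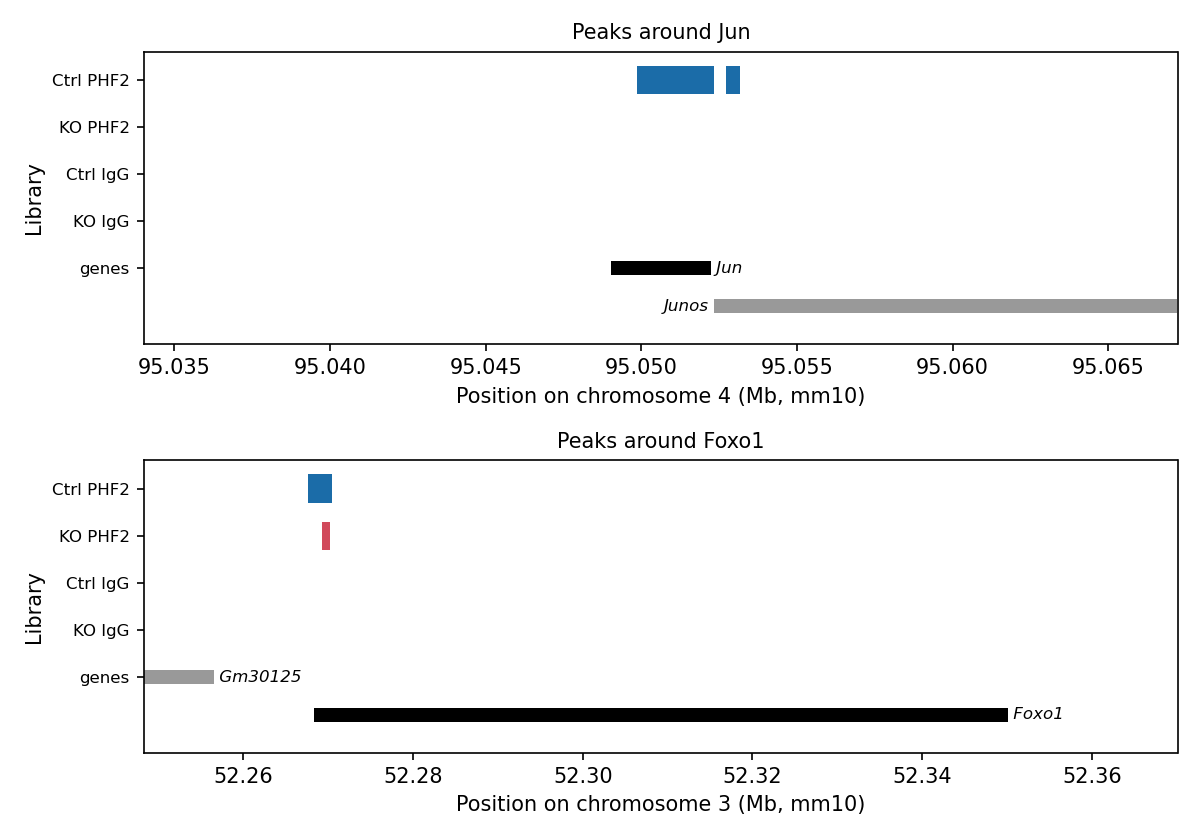
Peaks of the 4 libraries (coloured bars, y axis) and annotated genes (black for protein-coding, grey for non-coding) by position in Mb on mm10 (x axis) around Jun and Foxo1. At Jun the peaks drawn are in the Ctrl PHF2 library alone, while at Foxo1 the Ctrl and KO PHF2 libraries both have a peak at the lower end of the gene and the IgG libraries have none.

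Other shared Ctrl peaks of high fold enrichment, named after their values were seen, lay at Nudt4 (14.6), the transcription factor genes Sox4 (13.9) and Nfib (13.8), Zfp608 (13.6), the calmodulin gene Calm2 (13.6) and Trib1 (12.6). In the KO library 4 lists exceeded the central 95% of random lists, all on few genes: the atrophy list with Foxo1, Foxo3, Ddit4 and Cul1, the immediate early list with Dusp1, Klf6 and Myc, the satellite cell list with Hes1, Notch1 and Spry1, and the insulin list with Igf1r and Pik3r1. Sarcomere, excitation-contraction coupling, myogenic, glycolysis and splicing lists had 0 members at KO peaks, where random lists had upper limits of 1 or 2, so an absence was not detectable. The 39 KO PHF2 peaks with no Ctrl overlap had a median fold enrichment of 6.52. At gene ends they were led by the KIT ligand gene Kitl (10.3, chromosome 10, 100015952 to 100016663), Asap2 (7.55), Usp9x (7.55), the Hippo pathway kinase gene Lats2 (7.51) and the thrombomodulin gene Thbd (7.42).

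The third comparison set the PHF2 lists against the background given by IgG. IgG peaks lay mostly away from genes: 85.7% of Ctrl IgG and 82.2% of KO IgG peaks were intergenic. Genes were used on the autosomes, X and Y, and on these chromosomes alone the shares were 81.4% and 79.5%, against a median of 57.6% of random placements for both. Unplaced contigs held 13 and 17 of them, the mitochondrial chromosome 5 and 3, and the first 4 Mb of chromosome 9 another 15 and 19. Gene ends with an IgG peak were those of Lars2, the mitochondrial leucyl-tRNA synthetase gene, in both libraries, and of Wls and Usp3 in KO IgG. Of the 77 Ctrl IgG peaks, 68 (88.3%, Wilson interval 79.3 to 93.7) overlapped a KO IgG peak. By contrast, 0 of 1621 Ctrl PHF2 peaks overlapped an IgG peak, which allows a share of up to 0.185%, and 0 of 161 KO PHF2 peaks did, which allows up to 1.86%. The values of both PHF2 lists have the form given by calling against a control library, a step that removes regions high in that control. If that control was IgG, the lack of overlap may follow from the calling, and it does not measure specificity. No peak was found in all 4 libraries.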

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

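The common p threshold, the random lists matched on gene length and IgG peak location on nuclear chromosomes alone were chosen after seeing the data. No paired analysis was possible because each group held 1 library, and no library could be left out. The planned sequence composition and the random lists matched on CpG content were not run. Over the main values and counts, 55 alternatives stayed within their limits and 26 moved. Some of the 55 could not move, so the tally does not measure robustness. The PHF2 lists hold no peak off the autosomes, X and Y, and none that overlaps an IgG peak. KO PHF2 also keeps all its peaks at the p of its own weakest peak.

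With a -log10 q of at least 5, 852 Ctrl and 46 KO PHF2 peaks remained, fewer by construction. KO PHF2 then had fewer peaks than Ctrl IgG (70) and KO IgG (119), where the full list had more. The PHF2 values show scaling to a control library and the IgG values do not. The same q is therefore not a like threshold across these lists, and the counts do not rank PHF2 against background. The share of Ctrl PHF2 peaks with a KO peak, 7.03%, was 1.85% with reciprocal overlap of 50%, 9.13% with peaks within 1 kb, and 20.5% with the Ctrl list limited to the KO list's length. Ctrl-only peaks numbered 762 in the stronger 50% and 128 in the limited list, both shorter by construction. At gene ends, a 500 bp window gave 59.96% of Ctrl PHF2, 47.8% of KO PHF2, 0% of Ctrl IgG, 0.658% of KO IgG, 59.8% of Ctrl-only and 62.3% of shared peaks. A 2.5 kb window gave 82.4% of Ctrl PHF2, 78.9% of KO PHF2, 82.3% of Ctrl-only and 82.5% of shared peaks. With all annotated genes the shares were 76.8% of Ctrl PHF2, 76.5% of Ctrl-only, 11.7% of Ctrl IgG and 7.89% of KO IgG peaks. By summit alone they were 65.1% of Ctrl PHF2, 54.7% of KO PHF2, 65.03% of Ctrl-only and 66.7% of shared peaks. Wider windows and more genes can only raise these shares, and a narrower window or the summit alone can only lower them. The sizes of the shifts do not follow from this. From 71.0% of Ctrl PHF2 and 64.6% of KO PHF2 peaks, the KO share fell further at 500 bp and by summit. The reason was not tested.

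Gene lists above the random range numbered 9 to 12 over the alternatives, against 11. Those below numbered 2, and 1 with lists matched on gene length, where keratins moved inside the range; the cause was not tested. For single lists, 8 alternatives ended a call and 5 made one: histone genes under 3 settings, cell cycle genes by nearest gene, and satellite cell markers with all Ctrl PHF2 peaks. Summits of 8 to 44 tags limit every Ctrl PHF2 value, and single libraries limit every comparison.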

Other observations

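Every test in this part was chosen after the result it bears on had been seen. Counted as a family, the Klf genes of Krüppel-like transcription factors were frequent at Ctrl PHF2 peaks. Of 17 Klf genes, 8 had a peak within 1 kb of an end (Klf3, Klf4, Klf6, Klf7, Klf9, Klf10, Klf12 and Klf13), against an upper limit of 3 in random lists. Klf4 and Klf6 were already counted among the immediate early genes. The peak at Klf9 covered 2761 bp on chromosome 19, from 23140803, with 38 tags at its summit, and overlapped a KO PHF2 peak. Kinase genes of the MAP kinase cascade had 8 of 43 members at Ctrl PHF2 peaks, against a limit of 6: Map2k1, Map2k3, Map2k4, Map2k6, Map3k5, Map4k3, Map4k5 and Mapk14. Solute carrier genes had 15 of 364 and Hox genes 1 of 39, both within the random range. The Klf and MAP kinase families were picked from 10 families looked at in this way.

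Some PHF2 peaks lay near the ends of non-coding genes. Some of these lay inside a protein-coding gene, as the peak near Gm35655 lay inside Tgfb2. No random placements were made for the count below, and it does not assign PHF2 to the non-coding genes. At 94 Ctrl PHF2 peaks and 9 KO PHF2 peaks, the gene end within 1 kb belonged to a non-coding gene and to no protein-coding gene. Among them were Zeb2os, antisense to the gene of the transcription factor ZEB2, with a fold enrichment of 9.92 and a KO PHF2 peak, and Sox6os, antisense to Sox6, at 10.9 without one. Around Irs1, the insulin receptor substrate gene, the Ctrl library had a peak of 3451 bp inside the gene (fold enrichment 6.74) and another at its end (3.71), and the KO library had none at the gene.

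The KO PHF2 library had 161 peaks against 1621 in Ctrl. A shallower KO library is argued against by the recovered ratio of library sizes, 1.013, and a stricter threshold by the ratio of Ctrl to KO peaks at a common p, 9.09. A less efficient KO experiment could not be excluded: it and the loss of PHF2 would both lower the tags at shared peaks, whose median ratio was 0.725. Loss of Phf2 from fibres stays open as the biological explanation, untested with 1 library per genotype.

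The KO peaks sat on a small set of Ctrl peaks. Peak strength may account in part for which ones. The share with a KO peak reached 20.7% in the group of Ctrl peaks with the most tags, of 5 groups, against 1.54% in the group with the fewest. Median widths in these groups were 1033 and 369 bp, and wider peaks meet an overlap more easily, so strength was not separated from width. Of the 100 Ctrl peaks of highest fold enrichment, 26 had a KO peak. Cells without Acta1-Cre, which keep Phf2, are another candidate source, if these peaks mark bound PHF2, which was not shown. Of 58 markers of endothelial, mesenchymal, immune and mural cells 0 had a KO PHF2 peak, but the random lists ran from 0 to an upper limit of 2, so the count decides nothing. Satellite cell markers had 3 of 14 (Hes1, Notch1 and Spry1), against an upper limit of 1. Pax7, Myf5, Calcr and other members of that list had no PHF2 peak at a gene end in either genotype. Satellite cells stay open as a source, and the count does not decide it.

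The KO IgG peak inside Phf2 is unusual for an IgG library. It was rank 1 by width, 1224 bp against a median of 226.5, and rank 8 by tags, 30, among the 72 KO IgG peaks on nuclear chromosomes that overlapped no Ctrl IgG peak. Chance position under even placement over the genome is argued against, as 0.00184 such peaks would be expected inside Phf2. The KO IgG list is not spread evenly, with 19 peaks in the first 4 Mb of chromosome 9. Chance under uneven placement was not tested. Phf2 DNA of another source, such as an amplified or cloned fragment, is a candidate explanation that stays open. The other 3 lists had 0 peaks in the gene, but a PHF2 list called against this library would lose one there, and no biological explanation was tested.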
